A study of Mus musculus with 8 samples.

How the data were processed

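RNA of NS5 cells, described in the labels as neural stem cells from mouse brain at embryonic day 11.5, was measured on 8 Affymetrix Mouse Genome arrays, 2 for each of 4 groups. Per the labels the cells were plated with EGF and FGF2 for 24 h, kept without growth factors for 4 h, and then held for 48 h in FGF2 or in TGF-beta1, each with or without ethanol at 400 mg/dl. The labels give the growth factor dose as 10 ng per ul, a unit that the values cannot check and that is high for these factors in culture, so the dose itself is uncertain. They do not say whether the 2 replicates of a group came from separate cultures, and name no scan date, hybridization batch or pairing of replicates. RNA was extracted with RNeasy columns and labelled as biotin cRNA by the standard Affymetrix protocol with 1 cycle of amplification.

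The deposited table holds 1 linear signal intensity per probe set and array, made with MAS5 and GCOS, for which the sources used here give no versions. The 2% trimmed mean over all probe sets was 500 on each array, so every array had been scaled to 1 target. There were no detection calls, and the scanned images were not analysed here. The number of arrays limits the precision of all values, and with 2 arrays in a group the spread comes from all groups together.

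Of 45101 probe sets, 64 were Affymetrix controls, 34958 had exactly 1 gene symbol, 932 had several and 9211 had none. Probe sets with several symbols or none were left out of the gene table, which held 18193 genes. Of the probe sets with 1 symbol, 34754 had an Entrez identifier present in the RefSeq gene table, from which positions were taken (GRCm38.p6), and 0 symbols were updated. For the 9012 genes with more than 1 probe set, the one with the highest mean log2 signal was used. Values were transformed as log2(signal + 23.66), the constant being the 25th percentile of all signals. Genes at or above the 40th percentile of the mean transformed value (6.402) were tested, which kept 10916 genes. Means and SD of signals are on the linear scale without the constant. No further normalization was applied.

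Genes were tested with limma 3.58.1 in R 4.3.3, with a model of 4 group means for all 8 arrays, 4 residual degrees of freedom and empirical Bayes moderation with a trend (4.929 prior degrees of freedom). SE are the moderated standard errors of log2 fold changes. P values were two-sided and adjusted by the Benjamini-Hochberg method over all genes within each of 6 comparisons: ethanol within FGF2, ethanol within TGF-beta1, the average of these, their difference (the interaction), and TGF-beta1 against FGF2 without and with ethanol. The threshold was an adjusted p of 0.05. The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

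The 32 gene lists, written by hand, covered G1/S regulators, CDK inhibitors and pocket proteins, DNA replication, G2/M and mitosis, TGF-beta targets, TGF-beta and BMP pathway components, Id and Hes genes, FGF-ERK feedback targets, FGF and EGF receptors and ligands, neural stem and radial glia markers, neuronal markers, astrocyte markers, oligodendrocyte lineage markers, pluripotency markers, mesenchymal and smooth muscle markers, endothelial markers, microglia and macrophage markers, extracellular matrix, integrins and cell adhesion, cholesterol and SREBP targets, ER stress and the unfolded protein response, oxidative stress and NRF2 targets, alcohol and aldehyde metabolism, p53 targets and apoptosis, DNA methylation and chromatin enzymes, one-carbon and methionine metabolism, hypoxia and glycolysis, interferon and inflammatory response, the Wnt pathway, the Notch pathway, neurotrophin and guidance genes, and cytosolic ribosomal proteins. Some genes stand in more than 1 list. The 29 lists with at least 5 members above the signal filter were tested with camera at a preset correlation of 0.01, which compares a list with the other genes, and adjusted over the lists within a comparison.

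Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 lists passed by camera in any comparison, where the preset correlation gave 9 within FGF2, 9 within TGF-beta1, 8 in the average, 5 in the interaction, and 10 and 3 for the growth factors without and with ethanol. Fry's directional test was passed by 4 lists within TGF-beta1, 3 in the average, 1 in the interaction and 1 for the growth factors without ethanol, and by 0 in the other comparisons. Its test for change in either direction was passed by 3 lists within FGF2, 6 within TGF-beta1, 6 in the average and 0 in the rest. The median, the mean and the camera direction of a list differed in sign for 9 lists within FGF2, 4 within TGF-beta1, 5 in the average, 7 in the interaction, and 6 and 5 for the growth factors without and with ethanol, 0 of them past camera.

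The genes named were chosen by rule. In the ethanol comparisons, their average and the growth factors without ethanol, up to 12 genes with the largest rise and 12 with the largest fall were taken among those past the threshold whose arrays did not overlap, or the 5 with the smallest p where fewer than 5 passed. The growth factors with ethanol allowed up to 5 each way, and the interaction up to 8. Up to 4 members of each list with the smallest p were added per comparison. Smad7, Skil, Tgfbi, Spry2, Spry4, Dusp6, Etv4, Etv5, Ccnd1, Cdkn1a, Cdkn2b, Dnmt1, Dnmt3a and Dnmt3b were always taken, and 1 further gene of the rule is not reported here. Expressed sequence tags and RIKEN clones were skipped.

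The procedure was tested on simulated data of the same size, with 200 changed genes in each of 20 draws and the fitted spread of each gene. In the average comparison it recovered 53.9% of 2-fold, 96.6% of 4-fold and 99.5% of 8-fold changes. Within FGF2 the shares were 15.7%, 82.9% and 98.0%, within TGF-beta1 15.9%, 82.4% and 98.2%, in the interaction 1.72%, 42.2% and 83.0%, for the growth factors without ethanol 14.3%, 82.0% and 97.5%, and with ethanol 17.1%, 81.0% and 97.7%. Of the calls, 6.25% to 7.42% were false with these spreads, which moderation had already narrowed, and 4.22% to 5.52% with spreads drawn from the fitted prior. Genes were drawn as independent and every array followed its label. These shares may therefore not hold where genes vary together or arrays go against their labels. A lowered G2/M list passed camera in 10 of 10 draws, and 0 of 280 unchanged lists did, with genes simulated as independent.

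The alternatives fixed beforehand were no added constant, a constant at the median, quantile or cyclic loess normalization, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set tested alone, moderation without the trend or robust, the replicate number as a term, a 2-fold threshold, each array left out in turn, and only the 4 arrays compared. After the data were seen, a fit without 2 doubted ethanol arrays and one with crossed replicate numbers were added.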

Results

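Transcript levels were measured on 8 Affymetrix mouse arrays hybridized with RNA of NS5 cells, a neural stem cell line of mouse that the labels describe as embryonic brain cells. The cells were held for 48 h in FGF2, a mitogen for neural stem cells, or in TGF-beta1, a cytokine that signals through Smad proteins. Ethanol at 400 mg/dl was present in one group of each growth factor, which made 4 groups of 2 arrays named FGF2, Ethanol and FGF2, TGF-beta1, and Ethanol and TGF-beta1. The labels do not say whether the replicates of a group were separate cultures, so the spread below is the spread between samples. Each array gave 1 signal for each of 45101 probe sets. The 2% trimmed mean was 500 on every array, the median signal ran from 50.6 to 86.5, and 40.1% to 46.6% of probe sets lay above a signal of 100. The number of arrays limits the precision of every value.

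In the groups without ethanol, Fn1 (fibronectin, a matrix protein) and Pmepa1 (a target of TGF-beta signalling) separated the growth factors. The Fn1 signal was 129 ± 13.6 in FGF2 and 3562 ± 773 in TGF-beta1 (mean ± SD, n = 2 each). The ethanol arrays labelled replicate 2 stood with their own growth factor, with an Fn1 signal of 116 in FGF2 and 8226 in TGF-beta1. The ethanol arrays labelled replicate 1 stood with the other one: the Fn1 signal was 6828 on the array labelled Ethanol and FGF2 and 124 on the array labelled Ethanol and TGF-beta1. Over 46 genes that separated the growth factors on the 4 arrays without ethanol, 82.6% lay on the TGF-beta1 side on the array labelled Ethanol and FGF2 replicate 1, and 4.35% did on the array labelled Ethanol and TGF-beta1 replicate 1. Every array was kept in the group its label gives. An exchange of arrays between the ethanol groups would leave the estimate averaged over both growth factors as it is, but not the spread on which its p values and calls rest. It would also alter each estimate for ethanol within 1 growth factor. Counts without these 2 arrays, the doubted arrays, therefore stand beside the counts with them.

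**Figure D1:**
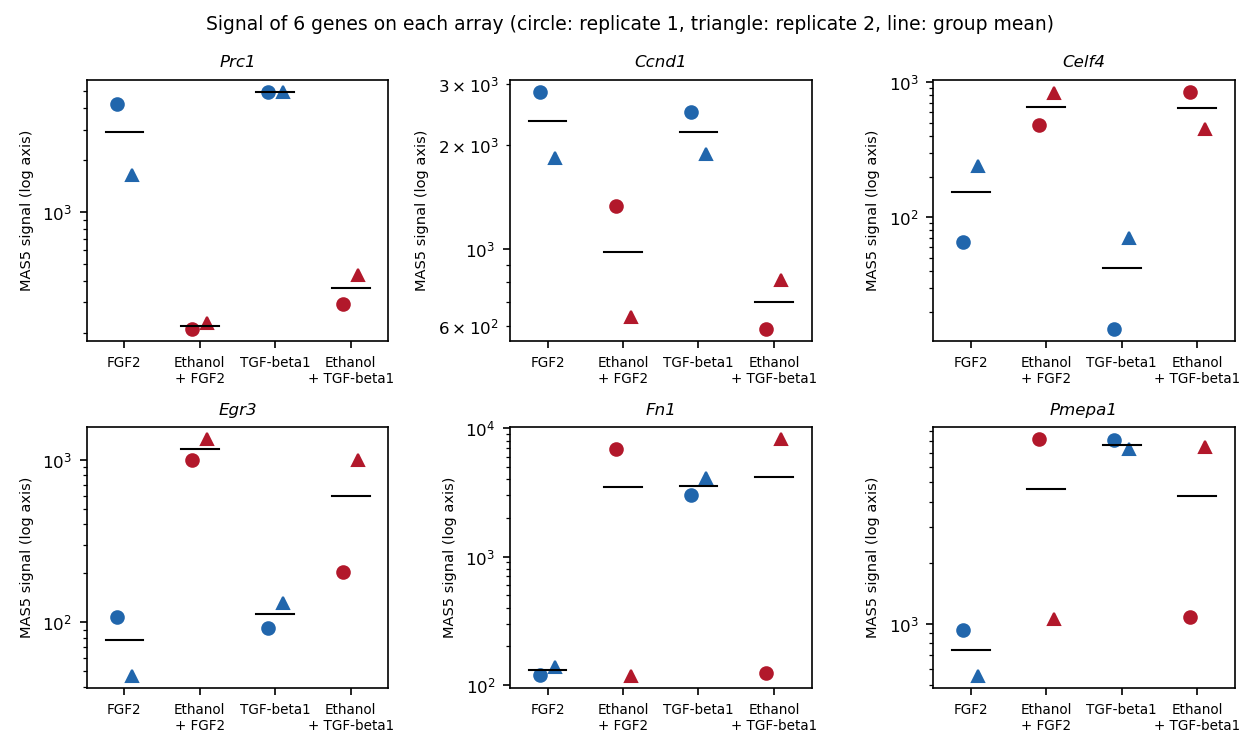
MAS5 signal (log axis) of 6 genes on each of the 8 arrays, by the group the label gives; circles are replicate 1, triangles replicate 2, lines the group mean (n = 2), blue without and red with ethanol. Prc1 lay between 209 and 433 on the 4 ethanol arrays and between 1646 and 4969 on the others, whereas Fn1 and Pmepa1 were high on 1 ethanol array of each growth factor.

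The first comparison asked how ethanol altered transcription in neural stem cells, averaged over both growth factors (4 arrays with and 4 without ethanol). Transcripts of the cell division machinery were lower with ethanol in this average. Of 10916 genes tested, 197 fell and 20 rose past an adjusted p of 0.05 by limma, and 183 of the falls and 12 of the rises were at least 2-fold. The Prc1 signal (a microtubule crosslinker of the dividing spindle) was 2926 ± 1810 in FGF2 and 218 ± 13.2 with ethanol added, and 4952 ± 23.6 in TGF-beta1 and 363 ± 99.2 with ethanol added (mean ± SD, n = 2 each). Its log2 fold change was −3.58 ± 0.28 (SE, adjusted p = 0.00247). Prc1 lies on chromosome 7 from 80294445 to 80316259 (GRCm38.p6).

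Of the G2/M and mitosis list, 24 of 26 measured members fell, all 26 when adjusted over the list alone, and the median was −3.17 (camera adjusted p = 9.55e-52, but adjusted p = 0.15 with an estimated correlation). Examples are Birc5 (the survivin subunit of the chromosomal passenger complex, log2 fold change −3.46 ± 0.31, adjusted p = 0.00247), Tpx2 (a spindle assembly factor, −3.57 ± 0.31, although 2 of its 4 probe sets went the other way) and Ttk (a spindle checkpoint kinase, −2.44 ± 0.22). Of the DNA replication list, 19 of 25 fell, 22 when adjusted over the list alone, with a median of 2.60-fold lower (camera adjusted p = 1.89e-32, adjusted p = 0.126 with an estimated correlation). They included Tk1 (thymidine kinase, −3.66 ± 0.44), Prim1 (a primase subunit, −2.04 ± 0.23) and the replicative helicase subunits Mcm3 (−1.92 ± 0.24) and Mcm6 (−1.88 ± 0.24). Of the G1/S regulators, 5 of 17 fell, 6 when adjusted over the list alone: Ccna2, Cdc6, Cdt1, Ccne1 and the cyclin D1 gene Ccnd1 (−1.45 ± 0.27, adjusted p = 0.0272). The Cdc6 signal was 1.81 and 10.4 in Ethanol and FGF2, under the added constant. The list median was −0.72 (camera adjusted p = 3.82e-10, adjusted p = 0.126 with an estimated correlation). By fry, which asks whether a list moves one way on balance, these 3 lists passed (adjusted p = 0.0149 each). On the array labelled FGF2 replicate 2 the G2/M list stood lowest of the arrays without ethanol, 1.23 log2 units below their mean.

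With the added constant of 23.66, the 12 largest falls among genes past the threshold were those of Knstrn (−3.78 ± 0.41), Pimreg, Cdca3, Tk1, Hmmr, Esco2, Prc1, Nusap1, Pbk, Tpx2, Kif11 and Ncapg (−3.53 ± 0.38), with adjusted p between 0.00247 and 0.00364. Signals of some of these genes lay near or under the constant with ethanol, as those of Esco2 (23.2 and 13.6) and Kif11 (22.5 and 40.8) in Ethanol and FGF2, so the size and order of these falls depend on it. Knstrn, Hmmr, Nusap1 and Kif11 act on the mitotic spindle, and Esco2 and Ncapg on chromatid cohesion and condensation. The 3 cell cycle lists held 68 tested genes, and 48 of the 197 falls were among them, where 1.23 would be expected by chance (Fisher's exact test, one-sided, p = 2.72e-70). That test treats genes as independent, and by camera with an estimated correlation these lists had adjusted p from 0.126 to 0.15. The other 149 falls lay outside these lists.

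**Figure D2:**
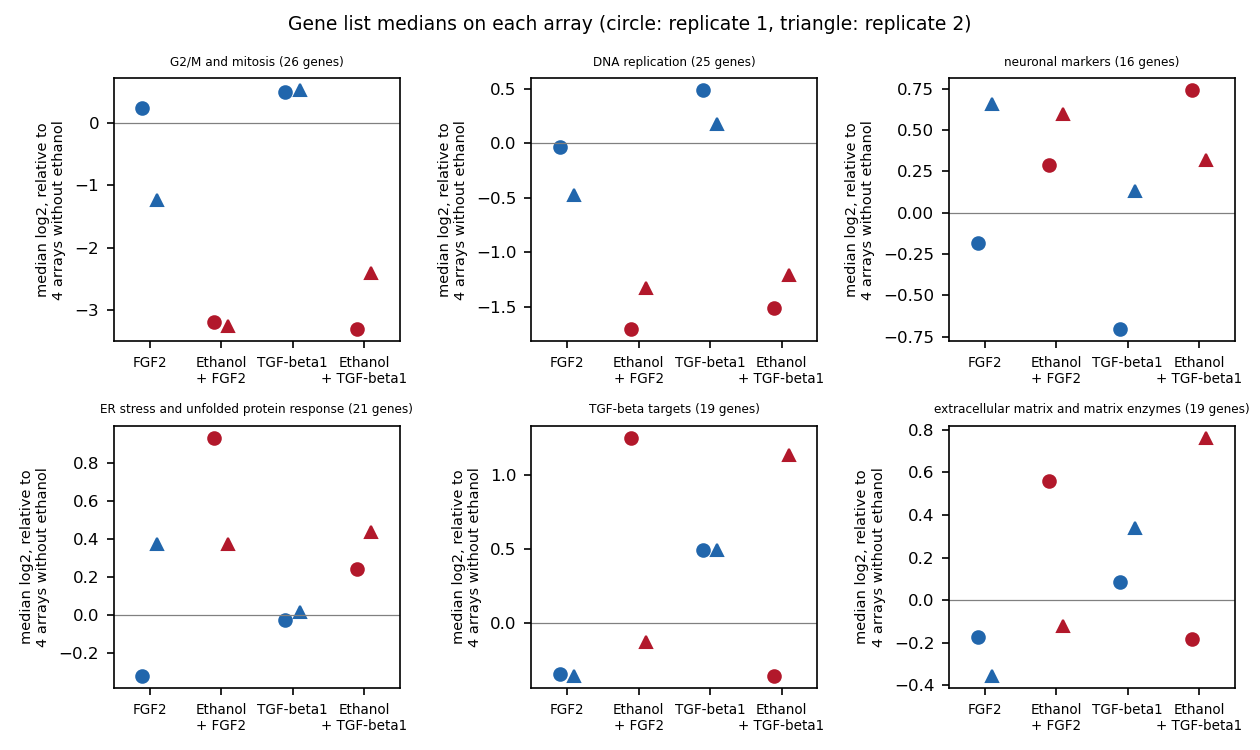
Median log2 value of 6 gene lists on each array relative to the mean of the 4 arrays without ethanol (y axis, log2), by the group the label gives; circles are replicate 1, triangles replicate 2, blue without and red with ethanol. The G2/M list lay at −2.40 or lower on the 4 ethanol arrays and at −1.23 or higher on the others, whereas the TGF-beta targets were high on 1 ethanol array of each growth factor.

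Among the rises were 2 neuronal markers and 2 immediate-early transcription factor genes. Of the neuronal markers, 2 of 16 rose, 4 when adjusted over the list alone: Celf4 (a neuronal RNA-binding protein on chromosome 18, 2.76 ± 0.44, adjusted p = 0.013) and Dlx2 (a homeobox gene of inhibitory neuron precursors, 0.91 ± 0.19, adjusted p = 0.0432). The list median was 0.55, with 14 of 16 members above 0 (camera adjusted p = 1.57e-05, adjusted p = 0.585 with an estimated correlation). The log2 fold changes of Tubb3 (neuronal tubulin) and Dcx (doublecortin) were 1.60 ± 0.39 and 1.56 ± 0.36, not past the test at adjusted p of 0.0938 and 0.0811. On the array labelled FGF2 replicate 2 the neuronal list stood 0.66 above the mean without ethanol, as high as on the ethanol arrays (0.29 to 0.74). The immediate-early genes Egr3 (2.73 ± 0.45, adjusted p = 0.0151) and Fosb (2.06 ± 0.34) rose, Egr3 by 1 of its 2 probe sets, and Egr2 had 2.52 ± 0.53 at an adjusted p of 0.0511. Without ethanol the Fosb signal was 26.22 and 3.04 in FGF2 and 23.7 and 43.19 in TGF-beta1, near or under the added constant. The Celf4 signal was 14.87 and 69.85 in TGF-beta1. The size of the Fosb and Celf4 rises therefore depends on the constant. The other large rises were those of Pak3, Col27a1, Nkain2 (1.58 ± 0.17, adjusted p = 0.00247), Sez6, Sorcs2, Ackr3 (1.36 ± 0.19, adjusted p = 0.00663), Insm1, Lrp1 and the nuclear RNA Malat1 (1.07 ± 0.22). With each array left out in turn, 22 of 25 named falls stayed past the threshold in all 8 fits (not Ccnd1, Ccne1 and Hells), but of 14 named rises only Ackr3 and Nkain2 did (Fosb passed the signal filter in 6 of these fits).

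None of the 21 genes of ER stress and the unfolded protein response passed the test, yet 20 lay above 0 with a median of 0.42 (camera adjusted p = 1.76e-05, adjusted p = 0.44 with an estimated correlation). Xbp1 and Herpud1 had 0.77 ± 0.25 and 0.56 ± 0.24. None of the 19 TGF-beta targets passed, with a median of 0.54 and 18 above 0 (camera adjusted p = 0.00255, adjusted p = 0.707 with an estimated correlation). That call ended without the array labelled Ethanol and FGF2 replicate 1 (median 0.15, adjusted p = 0.492) and without that labelled Ethanol and TGF-beta1 replicate 2 (0.17, adjusted p = 0.497). Of the DNA methylation and chromatin enzymes, 2 of 21 fell, 4 when adjusted over the list alone, with a median of −0.33 (camera adjusted p = 0.00255, adjusted p = 0.44 with an estimated correlation), which moved to −0.07 without the array labelled FGF2 replicate 1. The members that fell were Uhrf1 (−2.56 ± 0.23, adjusted p = 0.00247), which brings the maintenance methyltransferase to replicated DNA, and Hells (−1.53 ± 0.28), a remodelling helicase. Dnmt1, Dnmt3a and Dnmt3b themselves had −0.73 ± 0.17, 0.31 ± 0.16 and −0.57 ± 0.30, none past the test (adjusted p = 0.0878, 0.533 and 0.553). None of the 13 genes of one-carbon and methionine metabolism passed (median −0.36, camera adjusted p = 0.00973, adjusted p = 0.44 with an estimated correlation), and that call ended without the array labelled Ethanol and FGF2 replicate 2 (−0.21, adjusted p = 0.084) or Ethanol and TGF-beta1 replicate 1 (−0.17, adjusted p = 0.0543).

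The other 21 lists tested did not pass camera, and for 5 of them (oligodendrocyte, alcohol, hypoxia, interferon and Notch) the median, the mean and the direction by camera differed in sign. Extracellular matrix genes had a median of 0.26 (camera adjusted p = 0.0644), FGF and EGF receptors and ligands 0.25 (0.0702), cholesterol and SREBP targets −0.12 (0.0789), and cytosolic ribosomal proteins 0.21 (0.0973). The medians were 0.20 for astrocyte markers, 0.18 for neural stem and radial glia markers, 0.20 for integrins and cell adhesion, 0.20 for mesenchymal and smooth muscle markers, 0.12 for neurotrophin and guidance genes and 0.11 for p53 targets and apoptosis, at camera adjusted p between 0.121 and 0.482. The CDK inhibitors and pocket proteins had −0.03 (0.138), with 1 of 11 falling: Rbl1, the pocket protein p107 (−2.06 ± 0.26, adjusted p = 0.00457). Cdkn1a and Cdkn2b had −0.37 ± 0.40 and 0.61 ± 0.41, not past the test. The FGF-ERK feedback targets had 0.04, with Ccnd1 the 1 of 18 that fell, and Spry2, Spry4, Dusp6, Etv4 and Etv5 had adjusted p between 0.634 and 0.996. The Wnt list had −0.04, with 1 of 17 rising (Fzd3, a Wnt receptor, 0.79 ± 0.16, adjusted p = 0.0429). At camera adjusted p between 0.93 and 0.966 were the oxidative stress and NRF2 targets, TGF-beta and BMP pathway components, Id and Hes genes, alcohol and aldehyde metabolism, oligodendrocyte lineage, hypoxia and glycolysis, interferon and inflammatory, and Notch lists, with medians from −0.05 to 0.09. Of the mesenchymal and smooth muscle markers 10 of 21 passed the signal filter. Few endothelial, microglial and pluripotency markers did: 0 of 12 endothelial, 1 of 14 microglial (Cd68, 0.26 ± 0.33) and 4 of 15 pluripotency genes (median −0.11), too few for a set test.

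Without both doubted arrays, limma called 0 genes in this comparison (smallest adjusted p = 0.0611, 1150 genes at an unadjusted p under 0.05, 2 residual degrees of freedom). The G2/M list kept a median of −2.93 (camera adjusted p = 7.91e-37), with 26 of 26 members falling when adjusted over the list alone, and the neuronal list kept 0.38 (0.00136). With an estimated correlation their adjusted p were 0.512 and 0.777. The count was 92 without the array labelled TGF-beta1 replicate 1, 130 without that labelled Ethanol and TGF-beta1 replicate 1, and 119 under a stricter signal filter.

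Within TGF-beta1 (2 against 2 arrays as labelled, 1 of them doubted), cell division genes were again lower with ethanol. By limma 122 genes fell and 8 rose past the threshold, all at least 2-fold. The largest falls were those of Knstrn (−4.36 ± 0.57, adjusted p = 0.0195), Cdca3, Pimreg, Kif23, Ccnb2, Pttg1 (securin), Hmmr, Birc5, Cdkn3, Ncapg, Tk1 and Prc1 (−3.71 ± 0.40). Of the G2/M list, 20 of 26 fell, 26 when adjusted over the list alone (median −3.40, camera adjusted p = 1.75e-42, adjusted p = 0.208 with an estimated correlation). Of the DNA replication list, 8 of 25 fell, 22 when adjusted over the list alone (median −1.78, camera adjusted p = 8.24e-26, adjusted p = 0.189 with an estimated correlation), among them Mcm3 (−2.21 ± 0.34) and Mcm7 (−1.44 ± 0.23). Of the G1/S regulators, 4 of 17 fell, 6 when adjusted over the list alone (median −0.90, camera adjusted p = 7.6e-08, adjusted p = 0.189 with an estimated correlation).

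The 8 rises within TGF-beta1 were Celf4 (3.41 ± 0.62, adjusted p = 0.0403), Neurod4 (a proneural transcription factor, 2.78 ± 0.49), Dcx (2.70 ± 0.52, adjusted p = 0.0488), Sez6 (2.11 ± 0.34), Ackr3 (1.98 ± 0.27), Dtna (1.93 ± 0.30), Nkain2 (1.83 ± 0.24) and Ntn4 (1.74 ± 0.25). In TGF-beta1 the signals were 14.87 and 69.85 for Celf4 and 10.35 and 69.47 for Neurod4 (replicates 1 and 2). Those of replicate 1 lay under the added constant, so the size of these rises depends on it. Dcx, Dtna and Ntn4 had log2 fold changes of −2.30, −2.15 and −1.86 in TGF-beta1 against FGF2 without ethanol, none past the test, in a comparison that shares the TGF-beta1 arrays. Of the neuronal markers, 2 of 16 rose, 5 when adjusted over the list alone (median 0.80, camera adjusted p = 4.33e-07, adjusted p = 0.513 with an estimated correlation). Other lists past camera were ER stress (median 0.37, adjusted p = 0.0156), cholesterol and SREBP targets (−0.29, 0.0156), DNA methylation and chromatin enzymes (−0.25, 0.0163), neurotrophin and guidance genes (0.27, 0.0199) and FGF and EGF receptors and ligands (0.42, 0.0406). With an estimated correlation each of these 5 had an adjusted p of 0.513 or, for the receptors, 0.428. Their calls each ended without some single array, except that of the DNA methylation list. ER stress ended without the array labelled Ethanol and TGF-beta1 replicate 2 (0.21, adjusted p = 0.148). Cholesterol and neurotrophin genes ended without TGF-beta1 replicate 1 (−0.16, 0.448, and 0.11, 0.0976), and cholesterol genes also without Ethanol and TGF-beta1 replicate 2 (−0.14, 0.0797). Receptors ended without any of 4 arrays (both labelled Ethanol and FGF2, TGF-beta1 replicate 2 and Ethanol and TGF-beta1 replicate 1; adjusted p from 0.0558 to 0.109). By fry, the 3 cell cycle lists and alcohol and aldehyde metabolism passed (adjusted p = 0.0267 each), the last with 2 of 11 members falling when adjusted over the list alone and 0 over all genes by limma. That list did not pass camera (median −0.18, adjusted p = 0.244, and 0.513 with an estimated correlation). The Gapdh 3'/5' signal ratio, a measure of RNA integrity, was 1.93 and 2.06 in Ethanol and TGF-beta1 against 1.70 and 2.20 in TGF-beta1.

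Of the 130 genes, 124 also passed in the average, which shares these arrays. By limma the count was 0 without the array labelled TGF-beta1 replicate 1, TGF-beta1 replicate 2 or Ethanol and TGF-beta1 replicate 1 (521, 807 and 663 genes at an unadjusted p under 0.05). It was 67 without Ethanol and TGF-beta1 replicate 2 and by limma 0 without both doubted arrays (940 at an unadjusted p under 0.05, 1035 with all arrays). There 25 of 26 members of the G2/M list fell when adjusted over the list alone (camera adjusted p = 3.41e-30, but adjusted p = 0.476 with an estimated correlation and fry adjusted p = 0.311). It was 75 under the stricter signal filter, 85 with the mean of a gene's probe sets and 78 without the trend in limma.

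Within FGF2 (2 against 2 arrays as labelled, 1 of them doubted), the cell cycle lists had medians below 0 and passed camera at the preset correlation, but not with an estimated one (adjusted p = 0.205) or by fry (adjusted p from 0.0702 to 0.0759), and no single gene passed. Limma called 0 of 10916 genes, with 906 at an unadjusted p under 0.05 (441 higher, 465 lower, 546 expected by chance) and a smallest adjusted p of 0.0601. The 5 genes with the smallest p, none past the test, were Tpx2 (−3.54 ± 0.43), Prc1 (−3.46 ± 0.40), Aspm (−3.11 ± 0.43), Uhrf1 (−2.67 ± 0.33) and Dtl (−2.27 ± 0.31), each at an adjusted p of 0.0601. Adjusted over the list alone, 25 of 26 members of the G2/M list fell (median −2.85, camera adjusted p = 6.96e-43), 21 of 25 of the DNA replication list (−1.24, 1.56e-23) and 5 of 17 G1/S regulators (−0.80, 6.71e-07). Large estimates upward, none past the test, included those of Gfap (3.69 ± 1.2), Egr2 (3.65 ± 0.75, adjusted p = 0.116) and Ccn1 (3.61 ± 1.05). The Gapdh 3'/5' signal ratio was 3.33 and 3.48 in Ethanol and FGF2 against 1.64 and 2.20 in FGF2, so it was higher with ethanol where these lists were lower.

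Other lists past camera within FGF2 were the TGF-beta targets (median 1.08, adjusted p = 2.35e-05), ER stress (0.63, 7.78e-05), extracellular matrix (0.63, 0.00286), DNA methylation and chromatin enzymes (−0.25, 0.0219), cytosolic ribosomal proteins (0.28, 0.0427) and one-carbon metabolism (−0.41, 0.047), with 0 members past the test over all genes by limma. Each had an adjusted p of 0.696 with an estimated correlation. The TGF-beta and matrix calls rested on the array labelled Ethanol and FGF2 replicate 1, without which they had 0.38 (adjusted p = 0.232) and 0.20 (0.477). Without the array labelled FGF2 replicate 1, the ER stress list had 0.23 (0.212) and the DNA methylation list 0.01 (0.47), and the latter had −0.16 (0.158) without Ethanol and FGF2 replicate 2. The one-carbon call held only without Ethanol and FGF2 replicate 1 or TGF-beta1 replicate 2 and otherwise had adjusted p from 0.0522 to 0.664. The ribosomal call ended without FGF2 replicate 1, Ethanol and FGF2 replicate 1 or either array labelled Ethanol and TGF-beta1 (adjusted p from 0.0718 to 0.619). Under quantile normalization the ribosomal median was 0.02 (adjusted p = 0.95) and the direction by camera turned.

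The count of 0 within FGF2 became 76 without the array labelled FGF2 replicate 2, 15 without either array labelled Ethanol and TGF-beta1, 1 without FGF2 replicate 1, 29 under quantile normalization or without a signal filter, and 3 under the stricter filter (Prc1, Tpx2 and Uhrf1). Without both doubted arrays it was 0 by limma, with 612 at an unadjusted p under 0.05, and the G2/M list had a median of −2.71 (camera adjusted p = 4.7e-38, but adjusted p = 0.6 with an estimated correlation and fry adjusted p = 0.362).

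**Figure D3:**
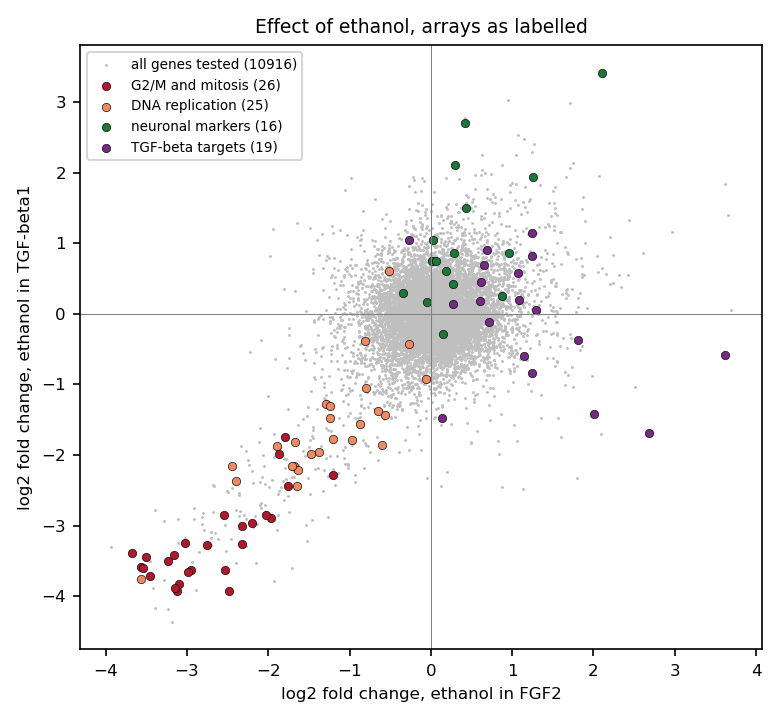
Log2 fold change with ethanol in FGF2 (x axis) against that in TGF-beta1 (y axis) for 10916 genes, arrays as labelled (2 against 2 on each axis); each point is a gene and colours mark members of 4 lists. The 26 G2/M genes lay below 0 on both axes, with medians of −2.85 and −3.40, whereas the TGF-beta targets spread to the right of 0 with a median of 1.08 in FGF2 and 0.14 in TGF-beta1.

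The interaction asked whether the growth factor altered the effect of ethanol, as the effect within TGF-beta1 minus that within FGF2. Across genes the effects, which share no array, had a Pearson r of 0.419 (Spearman's rho 0.147; genes are not independent replicates), and 128 of the 130 genes past the threshold within TGF-beta1 had the same sign within FGF2. By limma 0 genes passed the test of the difference, with 484 at an unadjusted p under 0.05 (546 expected by chance) and a smallest adjusted p of 0.831. Among the lists, the TGF-beta targets had a median difference of −0.84 (camera adjusted p = 0.0229), neuronal markers 0.65 (0.0187), hypoxia and glycolysis −0.50 (0.031), Wnt 0.19 (0.0313) and neurotrophin and guidance genes 0.35 (0.0499), each with an adjusted p of 0.854 with an estimated correlation. Members with large estimates included Ccn1 (−4.19 ± 1.48) and Pmepa1 (−3.43 ± 1.40) of the TGF-beta targets and Dcx (2.29 ± 0.73) of the neuronal markers, none past the test. By fry only alcohol and aldehyde metabolism passed (median difference −0.21, fry adjusted p = 0.0186, camera adjusted p = 0.0686). With single arrays left out, the calls ended without TGF-beta1 replicate 1 or Ethanol and TGF-beta1 replicate 1 for all 5 lists (adjusted p from 0.0567 to 0.858). They also ended without FGF2 replicate 1 or Ethanol and FGF2 replicate 1 for the TGF-beta targets, hypoxia and Wnt. They ended without FGF2 replicate 2 for the neuronal (0.14, 0.362) and neurotrophin lists (0.01, 0.334), the latter also without Ethanol and FGF2 replicate 1 or Ethanol and TGF-beta1 replicate 2 (adjusted p = 0.23 and 0.0664). Without both doubted arrays, the difference was 0.28 for the TGF-beta targets (adjusted p = 0.0132, adjusted p = 0.655 with an estimated correlation), 0.26 for the neuronal markers (0.147), −0.03 for hypoxia (0.588), 0.18 for Wnt (0.349) and 0.01 for neurotrophin genes (0.346). Limma called 0 genes (212 at an unadjusted p under 0.05).

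The comparison of TGF-beta1 with FGF2 without ethanol uses none of the doubted arrays in its estimate, though they enter the shared spread. The lists of TGF-beta targets, matrix genes and the cell cycle had medians above 0 and passed camera at the preset correlation. None passed with an estimated correlation (adjusted p from 0.5 to 0.592), the matrix and G1/S calls ended with single arrays left out, and the G2/M median was 0.31 in place of 1.02 without FGF2 replicate 2. That correlation was estimated from the spread of all 8 arrays, the doubted ones included. For the TGF-beta targets, by which those arrays were singled out, it was 0.723, and −0.0532 without them. For the G2/M list it was 0.688, and 0.784 without them. The Pmepa1 signal was 741 ± 273 in FGF2 and 7704 ± 550 in TGF-beta1, and that of Gfap (an astrocyte filament protein) 298 ± 334 and 2281 ± 254 (mean ± SD, n = 2 each). With the spread shared by all 8 arrays, limma called 0 genes (542 at an unadjusted p under 0.05, smallest adjusted p = 0.322). The 5 with the smallest p were Ntn4, Dtna, Aldh1a1 (retinaldehyde dehydrogenase, 3.45 ± 0.52), Ccbe1 (−2.32 ± 0.43) and Pgpep1 (1.64 ± 0.31). With the 4 arrays compared fitted alone, limma called 5 genes, all higher in TGF-beta1: Aldh1a1 (adjusted p = 0.0129), Fn1 (4.54 ± 0.25, adjusted p = 0.0129), Mfap4 (4.59 ± 0.39), Pmepa1 (3.38 ± 0.28) and Susd5 (2.48 ± 0.21, each adjusted p = 0.0393). Mfap4, a microfibril protein, and Susd5 were named after their values were seen, since the rule for naming genes does not take them. The count was also 5 without both doubted arrays, where the SE of Fn1 was 0.25 against 1.93 with all arrays, as leaving out arrays chosen by Fn1 brings about.

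By list, the TGF-beta targets had a median of 0.94 (16 of 19 above 0, camera adjusted p = 0.000217, adjusted p = 0.592 with an estimated correlation). In it Smad7 was at 1.43 ± 0.57, Skil at 0.99 ± 0.33 and Tgfbi at −0.09 ± 0.59. The extracellular matrix list had 0.60 (0.00623, adjusted p = 0.592 with an estimated correlation). The matrix call ended without FGF2 replicate 1 or TGF-beta1 replicate 2 (adjusted p = 0.0622 and 0.0796). The G2/M list had a median of 1.02 with 26 of 26 members above 0 (camera adjusted p = 6.45e-14), which was 0.31 (0.00727) without the array labelled FGF2 replicate 2 and 1.82 without FGF2 replicate 1. DNA replication had 0.56 (6.63e-07), which was 0.32 without FGF2 replicate 2. Both had an adjusted p of 0.5 with an estimated correlation. The FGF-ERK feedback targets had −0.57 (0.00334, adjusted p = 0.5 with an estimated correlation), with Spry4 at −1.97 ± 0.59, Etv5 at −1.24 ± 0.28 and Dusp6 at −0.94 ± 0.47, none past the test. That call ended without FGF2 replicate 1 (−0.60, adjusted p = 0.233). The neuronal markers had −0.40 (0.00079), the CDK inhibitors and pocket proteins 0.74 (0.00623), and the NRF2 targets −0.10 (0.0202), each with an adjusted p of 0.592 with an estimated correlation. Without FGF2 replicate 2 these were 0.02 (0.575), 0.24 (0.575) and 0.03 (0.777), and without TGF-beta1 replicate 1 they had adjusted p of 0.258, 0.183 and 0.313. The G1/S regulators had 0.31 (0.0292) and the Wnt list −0.22 (0.00713), each with an adjusted p of 0.5 with an estimated correlation. They ended without FGF2 replicate 1 (0.42, 0.0622, and −0.26, 0.0508). The G1/S call also ended without FGF2 replicate 2, Ethanol and FGF2 replicate 2 or TGF-beta1 replicate 1 (adjusted p from 0.0559 to 0.461). Adjusted over the list alone, 2 of 11 alcohol and aldehyde metabolism genes rose, a list that passed fry (fry adjusted p = 0.0291) but not camera (median 0.18, adjusted p = 0.0759).

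With ethanol present, the growth factor groups as labelled did not separate in the genes that separated them without it, and both doubted arrays lie in this comparison. The Fn1 signal was 3472 ± 4750 in Ethanol and FGF2 and 4175 ± 5730 in Ethanol and TGF-beta1 (mean ± SD, n = 2 each). Limma called 0 genes (288 at an unadjusted p under 0.05, smallest adjusted p = 0.983). The 5 with the smallest p were Piezo1 (a mechanosensitive channel, −2.02 ± 0.45), Adi1 (1.45 ± 0.35), Zkscan17 (−0.88 ± 0.21), Mlf1 (1.97 ± 0.48) and Mboat1 (1.71 ± 0.43). The signals of Mlf1 (9.06 ± 8.42) and Mboat1 (7.63 ± 7.77, mean ± SD, n = 2 each) in Ethanol and FGF2 lay under the added constant of 23.66, which sets the size of these differences. Across genes, the growth factor effects with and without ethanol had a Pearson r of −0.0621 and a Spearman's rho of −0.140. Past camera were the G2/M list (median 0.57, adjusted p = 1.27e-05), cytosolic ribosomal proteins (−0.36, 0.00397) and neurotrophin and guidance genes (0.29, 0.0103), each with an adjusted p of 0.838 with an estimated correlation. The first ended without Ethanol and TGF-beta1 replicate 2 (0.24, 0.213), and the others without Ethanol and FGF2 replicate 1 (−0.13, 0.261, and −0.02, 0.261). The ribosomal call also ended without Ethanol and TGF-beta1 replicate 2 (−0.14, 0.342). The TGF-beta targets had −0.05 (0.858). Their median was 1.34 without both doubted arrays, which were singled out by such genes.

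Without both doubted arrays, 1 array remained in each ethanol group, assumed to vary like the other groups. Limma then called 2 genes, Fn1 (5.88 ± 0.35, adjusted p = 0.0218) and Susd5 (4.36 ± 0.30, adjusted p = 0.0269), both higher in TGF-beta1. These arrays were left out because Fn1 and TGF-beta targets went against their labels, so that these genes separate without them follows from the choice and is no separate evidence.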

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

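The tests of the exchange of labels, of a batch shared by arrays of both ethanol groups, of an altered response to the growth factor and of a batch of the ethanol arrays were chosen only after the results were seen, as was leaving out the doubted arrays (the ethanol arrays labelled replicate 1).

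At the preset correlation, 5 gene lists passed the camera test of the difference between the ethanol effects in the growth factors, but with an estimated correlation each had an adjusted p of 0.854. By limma 0 genes passed (484 at an unadjusted p under 0.05). Only these 5 lists were followed without the doubted arrays, though other lists differed there too. The Id and Hes genes then had a median difference of −0.68 (9 of 9 members below 0), against −0.59 with all arrays. For the NRF2 targets it was 0.26 without the doubted arrays and −0.002 with all. The alcohol and aldehyde list had −0.47 without them and −0.21 with all. The median difference was −0.841 for the TGF-beta targets (adjusted p = 0.0229), and 0.277 without the doubted arrays (0.0132, adjusted p = 0.655 with an estimated correlation), which is the opposite direction. For the neuronal markers it was 0.654 (0.0187), and 0.257 without them (0.147). Hypoxia and glycolysis had −0.504 (0.031), and −0.0331 without them (0.588). The Wnt list had 0.185 (0.0313), and 0.177 without them (0.349). Neurotrophin and guidance genes had 0.35 (0.0499), and 0.0144 without them (0.346). The doubted arrays were singled out by TGF-beta targets, so the value of that list without them is not independent of the choice.

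The first pattern is the fall of mitosis genes on the ethanol arrays. With the 3'/5' signal ratio as a covariate for RNA quality, the mean log2 effect over the G2/M list was −2.79 ± 0.53 (SE), against −2.97 ± 0.38 without it, and with the spike signal as a covariate for array brightness it was −2.86 ± 0.32, so neither trend accounts for the whole fall. By an additive model for ethanol the real split called 238 genes, and 1 of 35 splits of the 8 arrays into 4 and 4, the real one, called as many. This argues against chance but cannot exclude it, since 35 splits are few. The count covers all genes, so it is no test of the mitosis list itself. The highest other split called 74 genes. It set both FGF2 arrays, Ethanol and FGF2 replicate 2 and Ethanol and TGF-beta1 replicate 1 against the rest. That is the split by growth factor if the doubted arrays were exchanged. The split by growth factor as labelled, fitted without a further growth factor term, called 0 genes. The labels name a batch or date for 0 arrays, so a separate batch for the ethanol arrays cannot be told apart from ethanol itself, which stays open as the biological explanation.

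The second pattern is that the ethanol arrays labelled replicate 1 stand with the other growth factor, which was seen in TGF-beta targets, so it was tested on the 10831 genes outside the growth factor score and the TGF-beta target, matrix and mesenchymal lists. An exchange between the groups (a mislabelled sample and its partner) stays open. The criterion written for it counts both arrays of 1 group lying opposite to their label as against an exchange. The projection ran from 0 at the FGF2 mean to 1 at the TGF-beta1 mean of the arrays without ethanol. On it, 2 of the 4 ethanol arrays lay nearer the other growth factor, both labelled Ethanol and TGF-beta1 (−0.13 and 0.422). Those labelled Ethanol and FGF2 lay at 0.483 and −0.0463. The outcome therefore met the side of the criterion against an exchange, but by values near the midpoint. The values 0.422 and 0.483 are closer to the midpoint than the gap of 0.437 between FGF2 replicates, so neither side is settled. The side of the midpoint also cannot decide, since these genes include cell cycle genes, higher in TGF-beta1 (G2/M median 1.02) and lower with ethanol. Among the ethanol arrays alone, Ethanol and FGF2 replicate 1 and Ethanol and TGF-beta1 replicate 2 lay highest, the order an exchange would give. A shared batch unrelated to the growth factor is argued against by an r of 0.454 across these genes between the difference of the array pairs and the TGF-beta1 effect without ethanol, where the other pairings gave −0.0789 and −0.00989, although the pairing was formed after its TGF-beta targets were seen. An altered response to the growth factor under ethanol would move both arrays of a group alike. On the TGF-beta target list, arrays of an ethanol group differed by 1.39 and 1.72 (at most 0.099 without ethanol). That argues against it for these genes, although they are the ones that raised the doubt. On the projection the gaps were 0.529 and 0.552 (0.437 without ethanol), so over the other genes it stays open. The Gapdh 3'/5' ratio went with the labels (3.33 and 3.48 in Ethanol and FGF2, 1.93 and 2.06 in Ethanol and TGF-beta1). So did the actin ratio (3.57 and 4.20, against 2.78 and 3.07). Taken alone, this goes against an exchange of whole arrays. Without ethanol, however, the Gapdh ratio went with the replicate number (1.64 and 1.70 in replicate 1, 2.20 and 2.20 in replicate 2), so it cannot decide.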

How the results depend on the processing

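The fits without both doubted arrays (the ethanol arrays labelled replicate 1) and with crossed replicate numbers were chosen after seeing the data. Over all alternatives, the fold changes of named genes kept their sign in 16224 values and changed it in 292, of which 0 were past the limma test in either fit, while 102 newly passed it and 361 no longer did. List medians kept their sign in 3297 values and changed it in 293, of which 23 were past camera in at least 1 of the fits compared. With the camera direction kept, 117 list values newly passed camera and 112 no longer did, and 13 turned in camera direction and were past camera in at least 1 fit. Unless stated, the cause was not tested.

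Within FGF2 the count of genes past the test was 29 under quantile normalization, 29 with no filter, 3 with the filter at the 60th percentile and 70 in a block of crossed replicate numbers, and ran from 0 to 76 with 1 array left out. Within TGF-beta1 it was 75 with the 60th percentile filter, which tests fewer genes, 85 with the mean of probe sets, 78 without the trend, and 0 by limma in a replicate block (1026 at an unadjusted p under 0.05) or without both doubted arrays (940), with 0 to 162 when 1 array was left out. In the average it was 119 with that filter, 0 by limma without both doubted arrays (1150), and 92 to 231. The growth factors without ethanol gave 5 with only the 4 arrays compared and 5 without both doubted arrays, and with ethanol 2 without both.

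With 1 array left out, the lone array being assumed to vary like the other groups, the lists past camera numbered 5 to 13 within FGF2, 7 to 12 within TGF-beta1, 7 to 13 in the average, 0 to 7 in the interaction, and 6 to 12 and 3 to 11 for the growth factors without and with ethanol. The interaction had 2 with no filter, 1 with the mean of probe sets and 3 in a replicate block. The growth factors with ethanol had 11 without both doubted arrays.

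The ribosomal median within FGF2 was 0.0246 under quantile normalization. With 1 array left out, the TGF-beta targets ran from −0.68 to 0.84 within TGF-beta1, and from −0.96 to 0.49 between the growth factors with ethanol, where extracellular matrix ran from −0.50 to 0.49. ER stress ran from −0.43 to 0.32 without ethanol. Without both doubted arrays the interaction was 0.28 for the TGF-beta targets and −0.0331 for hypoxia, and with ethanol the growth factors differed by 1.34 for the TGF-beta targets, 0.75 for extracellular matrix, 0.22 for p53 targets and 0.34 for hypoxia. These arrays were left out because their TGF-beta targets went against their labels, so the values of those genes follow in part from that choice. Cyclic loess moved the median interaction over all genes to −0.10. Replicate numbers were not treated as pairs in the main fit, since deviations of replicate 1 correlated across genes at 0.466 between the groups without ethanol but at −0.438 between those with it. The second value cannot decide on pairing, since an exchange of the doubted arrays could itself turn its sign. Without ethanol, the 18S signal went with the replicate number (5147 and 5275 in replicate 1, 2344 and 2374 in replicate 2). The main comparison of the growth factors without ethanol therefore leaves out a pairing that those arrays may have. Signals near background limit genes below the filter, and also fold changes of genes above it whose signal in a group lay near or under the added constant, such as Esco2, Cdc6, Mlf1 and Mboat1. The same holds for the rises of Celf4, Neurod4 and Fosb, where signals without ethanol lay near or under the constant on at least some arrays.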

Other observations

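The arrays also differed in measures outside the comparisons. The actin 3'/5' signal ratio was 2.35 and 3.61 in FGF2, 3.57 and 4.20 in Ethanol and FGF2, 2.36 and 3.03 in TGF-beta1, and 2.78 and 3.07 in Ethanol and TGF-beta1. The signal of 18S ribosomal RNA was 5147 and 2344 in FGF2, 9922 and 5691 in Ethanol and FGF2, 5275 and 2374 in TGF-beta1, and 5440 and 5161 in Ethanol and TGF-beta1 (replicates 1 and 2). The pair of arrays with the highest Pearson r across genes was Ethanol and FGF2 replicate 2 with Ethanol and TGF-beta1 replicate 1 (0.982), and the replicates of a group had r of 0.94 in FGF2, 0.936 in Ethanol and FGF2, 0.969 in TGF-beta1 and 0.959 in Ethanol and TGF-beta1. Genes are not independent replicates in these correlations.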
